A study of Homo sapiens with 10 samples.

How the data were processed

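Single-cell RNA-seq was made with the 10x Genomics 3′ v3.1 chemistry from Kuramochi cells hashed with TotalSeq-A antibodies, per the labels' protocols. The 10 GEO samples are 8 gene expression libraries and 2 hashtag libraries of 2 pools, and each pool holds cells of all 5 conditions. None is of 1 condition, so the condition and pool of each cell were taken from its name in the deposited matrix. Cell Ranger 3.1, Seurat and the build hg38/GRCh38 are named per the submitters' processing notes, with no role given. Settings of counting, hashtag demultiplexing and cell filtering are not given in the sources used here.

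The deposited matrix holds UMI counts, not normalized by the authors, for 19893 genes in 13800 cells. Those cells are 7346 of 9780 barcodes in the deposited list of pool 1 and 6454 of 9117 of pool 2. No cell had fewer than 502 genes or more than 15.0% mitochondrial counts. Other values deposited by the authors, such as genes per cell and cell names, were used only to describe and match cells. A further deposited table, whose name ends in g1, lists 7762 of the cells (56.2%) without any other stated reason. Cells on it had 0.0506 MKI67 UMIs each on average against 2.39 in the others, and 96.8% of them were called G1 against 5.58%. All 13800 cells were therefore used, and the listed ones formed an alternative. No doublet caller was run: hashtags can remove doublets between conditions but not within one, and whether the authors removed them is not given. The most UMIs in a cell were 20334 in pool 1 and 24458 in pool 2. Deposited hashtag sequences were not used here.

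Counts were summed over the cells of each condition and pool. The 10 sums were scaled with trimmed mean of M-values (factors 0.868 to 1.11), genes were filtered with filterByExpr by condition, and the remaining 13330 genes were tested with edgeR 4.0.16 in R 4.3.3 by robust quasi-likelihood fits of all sums with 1 mean per condition. That left 5 residual degrees of freedom and a biological coefficient of variation of 4.39%. The 9 comparisons set each treated condition against control, adapted against persister cells at each dose, the doses against each other among persister and adapted cells, and the 2 dose effects against each other. Genes with a Benjamini-Hochberg adjusted p under 0.05 in a comparison count as changed. Nothing in the sources used here says that the 2 pools came from separate cultures, so p-values measure the spread between 2 pools, which may be technical. Between pools, chi-square per degree of freedom over genes of at least 100 counts was 2.18 to 3.37, against 1.15 to 3.03 between random parts of 1 sum, so no sum was counted as a copy of another. Same-numbered sums deviated together, with correlations across 2730 genes of 0.333 to 0.607 between the pool differences of every pair of conditions, and the pool was fitted as a replicate block as an alternative. Gene positions are from GENCODE 29 on GRCh38.

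Gene lists, 32 in all, were written from general knowledge, and some share members. They were tested with camera in limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01, again with an estimated correlation, and with the rotation test fry. The lists were S phase, G2/M phase, p53 targets, homologous recombination and Fanconi anemia, PARP inhibitor response, ABC transporters, interferon response, NF-kB and secreted inflammatory factors, MHC class I presentation, integrated stress and unfolded protein response, NRF2 targets, heat shock, hypoxia and glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation, fatty acid synthesis, cholesterol biosynthesis, autophagy and lysosome, apoptosis regulators, epithelial, mesenchymal, TGF-beta and YAP targets, ovarian serous lineage, stem cell and aldehyde dehydrogenase, MYC targets and ribosome biogenesis, large ribosomal proteins, immediate early, metallothioneins, and leukocyte, fibroblast and mesothelial markers. Genes named in the text passed the test, had at least 50 CPM in the higher condition with every sum of 1 condition above every sum of the other, and were among the 10 largest rises or falls, or the 5 largest for the dose comparisons and the difference of dose effects. Clone names and LINC, RPL, RPS and MT- symbols were not named. Up to 4 members of a list with the lowest p and at least 20 CPM were named too, and 6 genes always: PARP1, PARP2, BRCA2, ABCB1, MKI67 and CDKN1A. Groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

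Cell cycle phases were called with scanpy 1.11.5 in Python 3.11.15 after thinning each cell to 3000 UMIs and scaling to 10000. The calls used the S phase and G2/M phase lists, so G1 cells are chosen by low scores of those genes. With 2 sums per condition an exact two-sided permutation test cannot go below 0.333. Sums held 3532281 to 23189583 UMIs, and a gene with up to 3 UMIs in a sum was read as at the floor. Intervals and floors cover counting error only. Cells of the 10 µM adapted condition were grouped by Leiden clustering at resolution 0.2 on 2000 variable genes, 20 principal components and 15 neighbours. Median log2 changes over windows of 100 neighbouring genes were set against 1000 shuffles of gene order.

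Tests were checked on simulated data with 50 genes changed by each of 1.25, 1.5, 2 and 4-fold. For 10 µM persister cells against control 14, 30, 41 and 50 of them were found, and 6 unchanged genes were called among 12320 tested. For 320 µM adapted cells 20, 40, 48 and 50 were found, and 18 unchanged were called among 12313, which was more than 0.05 of the calls made. A p53 list shifted by 1.5-fold passed camera in both (Benjamini-Hochberg adjusted p = 1.2e-50 and 1.0e-96), adjusted p = 9.5e-04 and 1.8e-04 with an estimated correlation, and 0 of the other 31 and 30 lists were called. Alternatives were relative log expression size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, the compared sums alone, the replicate block, a stricter cell filter, G1 cells alone, sums thinned to the smallest total, at least 2-fold changes and leaving out each sum. Chosen after seeing the data were scaling by library totals alone, the cells of the deposited list, and leaving out ribosomal protein and mitochondrially encoded genes.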

Results

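Kuramochi, a human high-grade serous ovarian cancer line with a mutated BRCA2 gene, was profiled by droplet single-cell RNA-seq after exposure to olaparib, an inhibitor of the DNA repair enzymes PARP1 and PARP2. Cells of 5 conditions were tagged with antibody hashtags and mixed into 2 replicate pools: drug-naive control cells, naive cells kept for 9 days in 10 µM or 320 µM olaparib (persister cells), and populations adapted to growth at 10 µM or 320 µM (adapted cells). No library belonged to a single condition, so the condition and pool of each cell were read from its deposited name. Counts were summed over the cells of each condition in each pool, which gave 10 sums with n = 2 per condition.

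Control cells numbered 2435 and 2155 in the 2 pools, against 300 and 263 persister cells at 10 µM, 742 and 606 persister cells at 320 µM, 1831 and 1584 adapted cells at 10 µM and 2038 and 1846 adapted cells at 320 µM. Their sums held 22252107 and 23189583 UMIs (unique molecular identifiers, 1 per captured transcript) in control, 3532281 and 3745019, then 8302810 and 8082859 in persister cells at 10 and 320 µM, and 15859741 and 15972992, then 18358406 and 19834403 in adapted cells. The 10 µM persister sums were therefore the shallowest, and 3 UMIs in them were worth 0.849 and 0.801 CPM (counts scaled to a common total). Median UMIs per cell were 8539 and 10000 in control and 12099.5 and 15213 in 10 µM persister cells. Gene levels below are CPM scaled with trimmed mean of M-values factors, as mean ± SD of n = 2 sums. In each pair the condition named first comes first, log2 changes carry the same direction, and changes were tested with edgeR with Benjamini-Hochberg adjustment. A number given for a gene without a unit is its log2 change. Where a list passed camera in the main fit and no p with an estimated correlation follows, its call held with that setting too.

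Fewer cells were called in S or G2/M phase after olaparib. At 3000 UMIs per cell these phases held 56.5 ± 1.20% (SD, n = 2) of control cells, 21.1 ± 0.168% of 10 µM and 23.3 ± 1.60% of 320 µM persister cells, 33.4 ± 2.57% of 10 µM adapted cells and 43.9 ± 1.29% of 320 µM adapted cells. Without thinning the shares were 56.1 ± 0.707%, 23.3 ± 1.42%, 23.5 ± 2.41%, 34.1 ± 1.44% and 45.3 ± 0.836% in the same order. In 320 µM adapted cells the S phase share was 13.7 ± 0.185% against 27.2 ± 1.36% in control, while the G2/M shares were 30.2 ± 1.10% and 29.3 ± 0.160%. Each sum of a treated condition lay below both control sums in the combined share, but an exact two-sided permutation test of 2 against 2 sums cannot give a p below 0.33, and no other test of the shares was made. MKI67, a protein of proliferating cells, stood at 155 ± 0.248 CPM in control, 34.8 ± 4.41 and 47.5 ± 0.272 in 10 and 320 µM persister cells, and 101 ± 8.40 and 103 ± 6.38 in 10 and 320 µM adapted cells. Phase calls also read free RNA, whose share was not measured. The 207 cells under 3000 UMIs were left out of the thinned shares: 11 and 18 of control, 27 and 25 and then 15 and 20 of 10 and 320 µM persister, and 35 and 21 and then 19 and 16 of 10 and 320 µM adapted cells.

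**Figure D1:**
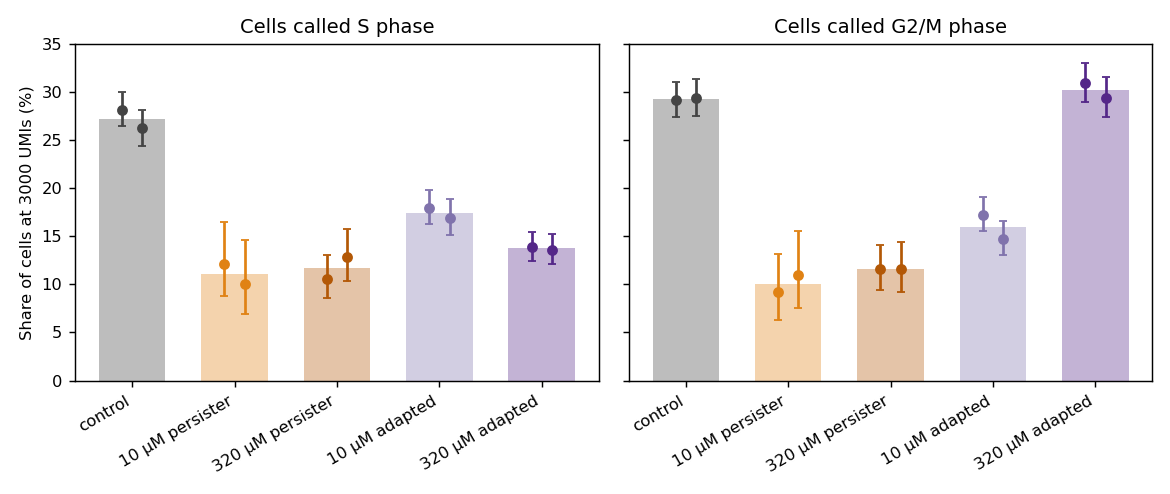
Share of cells called in S and in G2/M phase (percent, y axis) per condition (x axis) after thinning each cell to 3000 UMIs. Bars are means of 2 sums starting at 0, points are the sums, and their error bars are 95% Wilson intervals, which cover counting error only. In 320 µM adapted cells the G2/M mean of 30.2% stood beside the control's 29.3%, and their S phase means were 13.7% and 27.2%.

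PARP1, the main target of the drug, was lower in every treated condition, whereas the fall of PARP2 depended on which cells were used. PARP1 (GRCh38 chromosome 1, 226360691 to 226408079) went from 319 ± 6.29 CPM in control to 174 ± 2.74 and 217 ± 1.72 in 10 and 320 µM persister cells and to 166 ± 1.89 and 124 ± 0.566 in 10 and 320 µM adapted cells, log2 changes of -0.87, -0.56, -0.94 and -1.36. PARP2 went from 28.0 ± 0.240 CPM in control to 20.3 ± 0.135, 21.5 ± 0.0704, 23.8 ± 1.73 and 16.5 ± 0.584 in the same order. CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 14.8 ± 1.22 to 29.2 ± 0.584, 51.5 ± 7.58, 29.9 ± 0.0469 and 63.6 ± 0.732 CPM. BRCA2, mutated in this line (GRCh38 chromosome 13, 32315474 to 32400266), stood at 18.0 ± 0.620 CPM in control and 13.4 ± 3.66, 10.4 ± 0.767, 13.3 ± 0.811 and 19.8 ± 0.771 in the treated conditions, and the last of these was not past the test (edgeR, Benjamini-Hochberg adjusted p = 0.171). The BRCA2 window had -0.026, 0.089, -0.49 and -0.43. The call of the BRCA2 fall in 10 µM persister cells (-0.43) was lost without the control sum of pool 1 (-0.39) or the persister sum of pool 2 (-0.17). DESeq2 did not call it (-0.39, Benjamini-Hochberg adjusted p = 0.0983). Likewise the call of PARP2 in 10 µM adapted cells (-0.23) was lost without the control sum of pool 1 (-0.23) or the adapted sum of pool 2 (-0.16). Among G1 cells PARP2 was not called in 10 µM persister, 320 µM persister and 10 µM adapted cells (-0.043, -0.27 and -0.0076, edgeR, Benjamini-Hochberg adjusted p = 0.848, 0.118 and 0.964). Nor was it called in 320 µM persister cells of the deposited list (-0.22, adjusted p = 0.215). In 320 µM adapted cells BRCA2 turned to a fall past the test among G1 cells (-1.01, edgeR, Benjamini-Hochberg adjusted p = 5.8e-04) and in the cells of the deposited list (adjusted p = 0.00198). In the listed cells, nearly all called G1, BRCA2 was at 0.21 in 10 µM persister and -0.88 in 320 µM adapted cells. PARP2 was at 0.011 and 0.056 in 10 µM persister and adapted cells. Over all cells these were -0.43, 0.14, -0.46 and -0.23. ABCB1, a drug efflux pump that can export olaparib, had 0 UMIs in the control and persister sums, 0 and 1 in the 10 µM adapted sums and 2 in each 320 µM adapted sum, at or below the floor of 3 UMIs, and was not tested. A difference in ABCB1 was not detectable at this depth.

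The first question was what distinguishes cells that survive 9 days at the lower dose. In 10 µM persister cells interferon-induced and inflammatory genes rose from low levels. CXCL10, an interferon-induced chemokine (GRCh38 chromosome 4, 76021117 to 76023497), reached 785 ± 92.8 CPM against 3.48 ± 0.112 in control (log2 change 7.81). SAA1, an acute-phase protein, rose from 1.23 ± 0.0556 to 167 ± 0.0637 CPM (log2 change 7.07), and HP, which binds hemoglobin, went from 0.151 ± 0.0262 to 68.8 ± 18.7 CPM. CD74, the invariant chain of MHC class II (54.8 ± 10.8 against 0.325 ± 0.0402 CPM, log2 change 7.35), the antiviral gene RSAD2 (118 ± 39.5 against 0.607 ± 0.0791 CPM, log2 change 7.58), the iron-binding LCN2 (457 ± 83.9 against 2.46 ± 0.715 CPM, log2 change 7.54) and TRIM22 (52.3 ± 3.54 against 0.283 ± 0.10 CPM, log2 change 7.49) were also among the 10 largest rises. Reads of SAA1 and SAA2 can be exchanged between these near-identical genes, so the split between them is uncertain.

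All 44 measured interferon response genes rose (44 adjusted over the list alone, median log2 change 4.54, camera, Benjamini-Hochberg adjusted p = 1.7e-38). ISG15, a ubiquitin-like modifier, went from 179.9 ± 6.16 to 5798 ± 286 CPM, and IFI6, IFI27 and IFIT3 changed by 5.45, 4.74 and 5.29 on the log2 scale. All 27 genes of the NF-kB and secreted inflammatory list rose (27 adjusted over the list alone, median log2 change 4.92, or 4.64 with thinly counted members at their bound, camera, Benjamini-Hochberg adjusted p = 3.9e-22), among them the neutrophil chemokines CXCL8 (605 ± 9.28 against 6.48 ± 0.850 CPM, log2 change 6.54) and CXCL1 (1067 ± 7.47 against 9.38 ± 0.184 CPM, log2 change 6.83). All 17 genes of MHC class I presentation rose as well (17 adjusted over the list alone, median log2 change 2.99, camera, Benjamini-Hochberg adjusted p = 2.0e-14), including HLA-B (4.71), HLA-E (4.06) and the proteasome subunit PSMB9 (4.70), with the caveat that HLA genes share sequence. Of the 6 detected leukocyte markers, 3 rose and 0 fell, 3 and 0 adjusted over the list alone, which was not past the list test (camera, Benjamini-Hochberg adjusted p = 0.0754).

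Genes of the cell cycle fell. Of 43 S phase genes, 38 fell and 1 rose, 38 and 1 adjusted over the list alone (median log2 change -1.26, camera, Benjamini-Hochberg adjusted p = 8.0e-12, adjusted p = 0.119 with an estimated correlation). The replication factors CLSPN and MCM4 were at -1.43 and -1.40. Of 54 G2/M genes, 53 fell and 1 rose, 53 and 1 adjusted over the list alone (median log2 change -1.61, camera, Benjamini-Hochberg adjusted p = 7.5e-25). TOP2A was at -1.98 and CENPF at -2.17. In the homologous recombination and Fanconi anemia list 23 of 31 fell and 0 rose, 24 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.1e-05, adjusted p = 0.119 with an estimated correlation). MRE11 was at -1.36 and XRCC2 at -2.00. All 41 large ribosomal protein genes fell (41 adjusted over the list alone, median log2 change -0.88, camera, Benjamini-Hochberg adjusted p = 4.7e-31, adjusted p = 0.0531 with an estimated correlation). Ribosomal protein genes held 13.1% and 13.9% of the UMIs of these sums against 23.8% and 24.0% in control. Nuclear oxidative phosphorylation genes fell, 45 of 51 lower and 2 higher (46 and 2 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 2.8e-15). So did all 13 mitochondrially encoded genes (median log2 change -0.52, 13 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 3.3e-10).

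Targets of NRF2, the regulator of the oxidative stress response, rose (17 of 23 rose and 2 fell, 17 and 2 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 2.0e-07). FTH1, the ferritin heavy chain, went from 5065 ± 30.0 to 39294 ± 430.4 CPM and was the most abundant transcript of these sums, though reads of its pseudogenes can be mixed with it. AKR1B1, an aldose reductase, changed by 2.41. Autophagy and lysosome genes rose (25 of 33 rose and 0 fell, 28 and 0 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 1.1e-08). The autophagy receptor SQSTM1 was at 2.34 and the protease CTSB at 2.37. In the hypoxia and glycolysis list 23 of 28 rose and 1 fell, 24 and 2 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.5e-09, adjusted p = 0.119 with an estimated correlation). Apoptosis genes leaned higher (12 of 23 rose and 4 fell, 12 and 4 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.00823, adjusted p = 0.0795 with an estimated correlation). The caspase activator BID was at 1.90 and the inhibitor BIRC3 at 5.77. Mesenchymal genes were higher on balance (13 of 28 rose and 7 fell, 13 and 7 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.0247, adjusted p = 0.165 with an estimated correlation). Fibronectin, encoded by FN1, rose most among those named (764 ± 68.4 against 14.2 ± 0.165 CPM, log2 change 5.75). Epithelial genes were higher on balance too (11 of 21 rose and 6 fell, 11 and 6 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.0304, adjusted p = 0.119 with an estimated correlation). The mucin MUC1 was at 4.62. With G1 cells alone neither of these 2 lists passed (camera, Benjamini-Hochberg adjusted p = 0.117 and 0.0625).

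The p53 target list did not pass (9 of 23 fell and 8 rose, 9 and 8 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.995), with a median of -0.081, which turned positive under library totals alone, and a mean of 0.076. Its members GDF15, a stress cytokine, and BTG2, an antiproliferative gene, went opposite ways (3.71 and -1.61). The heat shock list, with a median of -0.23 and a mean of 0.042, did not pass either (9 of 19 fell and 6 rose, 10 and 7 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.390). Among the largest falls were OSR2, a developmental transcription factor (5.04 ± 2.39 against 59.1 ± 2.87 CPM, log2 change -3.53), GSTM4, a glutathione transferase (-3.19), SOX5, a transcription factor (-3.11), NMU, a neuropeptide (-2.93), and PEG10, an imprinted gene (41.6 ± 2.79 against 263 ± 3.93 CPM, log2 change -2.66). The calprotectin subunits S100A8 and S100A9 had the largest fitted rises. S100A8 rested on 546 UMIs against 3 in control, a ratio of 1136 with an exact 95% counting interval of 387 to 5528. Its call was lost with the 4 compared sums alone (edgeR, Benjamini-Hochberg adjusted p = 0.109), with thinned sums (adjusted p = 0.135), with G1 cells (adjusted p = 0.0721) and with cells of the deposited list (adjusted p = 0.0710). In all, 7547 of 13330 genes changed, 3638 higher and 3909 lower. Library totals alone gave 4346 higher and 3212 lower, with the median of all genes moved by 0.12 on the log2 scale.

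The same question was asked at the higher dose. After 9 days at 320 µM the largest rises included stress-response genes. TPPP3, a tubulin-binding protein (GRCh38 chromosome 16, 67389809 to 67393535), rose from 6.45 ± 0.190 to 218 ± 1.55 CPM (log2 change 5.07). The stress cytokine GDF15 (90.4 ± 6.37 against 4.46 ± 0.298 CPM, log2 change 4.34), the stress-induced chromatin protein NUPR1 (81.9 ± 3.76 against 4.21 ± 0.430 CPM, log2 change 4.28), the pseudokinase TRIB3 (3.26) and ASNS, which makes asparagine (135 ± 2.86 against 18.8 ± 0.584 CPM, log2 change 2.84), rose with it. So did the hyaluronan receptor CD44 (172 ± 0.804 against 16.6 ± 0.000809 CPM, log2 change 3.37) and the tight junction protein CLDN4 (145 ± 11.1 against 18.4 ± 0.714 CPM, log2 change 2.98). Falls were led by APOA1, an apolipoprotein of high-density lipoprotein (8.58 ± 4.83 against 109 ± 9.93 CPM, log2 change -3.67), the matrix protein SPON1 (-2.93), GSTM4 (-2.91), LYPD1 (-3.53) and LEMD1 (-3.26).

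Of 31 integrated stress and unfolded protein response genes, 24 rose and 3 fell, 25 and 3 adjusted over the list alone (median log2 change 1.04, camera, Benjamini-Hochberg adjusted p = 4.6e-11, adjusted p = 0.0503 with an estimated correlation). DDIT4 was at 2.51, CHAC1 at 3.26 and the serine synthesis enzyme PSAT1 at 1.23. Among NRF2 targets 18 of 23 rose and 1 fell, 18 and 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.7e-08, adjusted p = 0.0503 with an estimated correlation). FTH1 (19168 ± 737 against 5065 ± 30.0 CPM, log2 change 1.92) and TXNRD1 (1.19) were among them. Autophagy and lysosome genes rose too, 26 higher and 3 lower of 33 (27 and 3 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 3.2e-09, adjusted p = 0.0503 with an estimated correlation). The lysosomal sialidase NEU1 was at 1.52. Metallothioneins, which bind metal ions, fell (4 of 5 fell and 0 rose, 4 and 0 adjusted over the list alone, median log2 change -1.93, or -1.86 with thinly counted members at their bound, camera, Benjamini-Hochberg adjusted p = 0.00111, adjusted p = 0.0779 with an estimated correlation). MT2A went from 939.9 ± 38.0 to 214 ± 7.07 CPM, although reads can be shared within this family.

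Cell cycle lists were lower again. For S phase genes 38 of 43 fell and 0 rose, 38 and 0 adjusted over the list alone (median log2 change -0.76, camera, Benjamini-Hochberg adjusted p = 9.4e-12, adjusted p = 0.157 with an estimated correlation). For G2/M genes 52 of 54 fell and 1 rose, 52 and 1 adjusted over the list alone (median log2 change -1.30, camera, Benjamini-Hochberg adjusted p = 5.7e-28, adjusted p = 0.0503 with an estimated correlation). CDC20, an activator of mitotic exit, was at -2.20. MYC targets and ribosome biogenesis genes fell (24 of 32 fell and 0 rose, 24 and 0 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 2.6e-08, adjusted p = 0.0503 with an estimated correlation). The nucleolar proteins NCL and FBL were at -1.19 and -1.06. Large ribosomal protein genes went both ways, 12 higher and 12 lower (12 and 12 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.990). The heat shock list fell (13 of 19 fell and 3 rose, 13 and 3 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 1.1e-04, adjusted p = 0.0779 with an estimated correlation). HSPA8 was at -1.06. Immediate early genes fell (12 of 21 fell and 5 rose, 13 and 5 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.0152, adjusted p = 0.255 with an estimated correlation). FOSB was at -1.76. Ovarian serous lineage genes were lower (12 of 15 fell and 0 rose, 12 and 0 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 4.1e-05, adjusted p = 0.179 with an estimated correlation), among them WT1 (-2.31). Interferon response genes fell (26 of 44 fell and 3 rose, 26 and 3 adjusted over the list alone, median log2 change -0.72, or -0.65 with thinly counted members at their bound, camera, Benjamini-Hochberg adjusted p = 6.3e-05, adjusted p = 0.179 with an estimated correlation). IFITM3 went from 289 ± 9.17 to 76.9 ± 4.51 CPM. The NF-kB list did not pass (10 of 27 fell and 0 rose, 10 and 0 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.0548). In all, 7282 of 13330 genes changed, 3512 higher and 3770 lower, against 3940 higher and 3322 lower under library totals alone. With an estimated correlation 0 of the 17 list calls passed camera after adjustment, which left 9 lists at an unadjusted p under 0.05, while 27 passed in the rotation test fry.

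Persister cells at the 2 doses were then compared. At 320 µM all 44 interferon genes were lower than at 10 µM (44 adjusted over the list alone, median log2 change -5.20, or -4.96 with thinly counted members at their bound, camera, Benjamini-Hochberg adjusted p = 4.3e-43). ISG15 stood at 148 ± 6.64 against 5798 ± 286 CPM, SAA1 at 0.519 ± 0.239 against 167 ± 0.0637 (log2 change -8.31) and HP at 0.116 ± 0.00126 against 68.8 ± 18.7. NF-kB genes followed (26 of 27 fell and 0 rose, 27 and 0 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 6.5e-24). MHC class I genes were lower as well (17 of 17 fell and 0 rose, 17 and 0 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 1.7e-18). So were metallothioneins (5 of 5 fell and 0 rose, 5 and 0 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 1.5e-04). Higher at 320 µM were TPPP3 (218 ± 1.55 against 9.10 ± 0.983 CPM, log2 change 4.58), the transcription regulator ID2 (2.67), DOK5 (2.71) and AMN1 (2.83). All 41 large ribosomal protein genes were higher (41 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 3.6e-39). So were all 13 mitochondrially encoded genes (13 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 6.7e-14). Higher too were 40 of 51 nuclear oxidative phosphorylation genes (40 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 8.3e-15). Hypoxia and glycolysis genes were lower (23 of 28 fell and 1 rose, 23 and 1 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 4.5e-11, adjusted p = 0.113 with an estimated correlation). HP rested on 549 UMIs against 2 at 320 µM, a ratio of 412 at the floor of 3 UMIs and of 618 as counted, with an exact 95% counting interval of 170.3 to 5116. The call of S100A8 was lost without the 320 µM persister sum of pool 1 (-7.14) or of pool 2 (-12.9). Both it and S100A9 were lost with the 4 compared sums alone (edgeR, Benjamini-Hochberg adjusted p = 0.173 and 0.0709). In all, 6624 of 13330 genes changed, 3367 higher and 3257 lower, against 2944 and 3607 under library totals alone.

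Adapted populations were then compared with naive cells. At 10 µM several matrix genes were among the largest rises. At 3000 UMIs per cell 15.2% and 16.6% of cells in pools 1 and 2 had a COL1A1 UMI. COL1A1, a fibrillar collagen (GRCh38 chromosome 17, 50183289 to 50201632), rose from 1.04 ± 0.214 to 92.2 ± 1.99 CPM (log2 change 6.46), and the adhesion molecule VCAM1 from 0.517 ± 0.168 to 105 ± 4.50 (7.64). The matrix genes TGFBI (127 ± 0.154 against 1.15 ± 0.0644 CPM, log2 change 6.78), BGN (58.4 ± 4.66 against 1.13 ± 0.156 CPM, log2 change 5.69) and FN1 (665 ± 28.7 against 14.2 ± 0.165 CPM, log2 change 5.55) rose with them, as did smooth muscle actin ACTA2 (5.48) and the TGF-beta co-receptor ENG (5.37). Genes that fell most were the filaggrin gene FLG (1.78 ± 0.672 against 58.5 ± 0.741 CPM, log2 change -5.03), APOA1 (-4.55), the lineage transcription factor SOX17 (16.4 ± 2.56 against 325 ± 50.2 CPM, log2 change -4.31), the surface protein CD24 (-4.27), the desmosome protein DSP (-3.74), NMU (-3.45) and BTG2 (-2.56).

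Of 28 mesenchymal genes, 24 rose and 2 fell, 24 and 2 adjusted over the list alone (median log2 change 2.04, camera, Benjamini-Hochberg adjusted p = 6.9e-09, adjusted p = 0.117 with an estimated correlation). In the fibroblast marker list, which shares members with it, 11 of 13 rose and 1 fell, 11 and 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 6.5e-04, adjusted p = 0.156 with an estimated correlation). TGF-beta and YAP targets rose (14 of 25 rose and 7 fell, 14 and 7 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.0149, adjusted p = 0.188 with an estimated correlation). The receptor kinase AXL was at 4.38 and TGFB1 at 3.44. Epithelial genes split, 8 higher and 12 lower (8 and 12 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.537). KRT7 was at 3.86 and CLDN3 at -1.61. Mesothelial markers were lower (6 of 10 fell and 2 rose, 6 and 2 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.0359, adjusted p = 0.194 with an estimated correlation). WT1 was at -3.72. The stem cell and aldehyde dehydrogenase list did not pass (8 of 18 rose and 6 fell, 8 and 6 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.90), although CD44 was higher (2.16) and ALDH1A2, a retinoic acid enzyme, lower (-4.69). ABC transporters did not pass either (3 of 13 rose and 3 fell, 3 and 3 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.90), with a median of -0.045 and a mean of 0.13.

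Large ribosomal protein genes rose (37 of 41 rose and 1 fell, 37 and 1 adjusted over the list alone, median log2 change 0.45, camera, Benjamini-Hochberg adjusted p = 4.2e-16, adjusted p = 0.188 with an estimated correlation). Fatty acid synthesis genes rose (10 of 16 rose and 2 fell, 10 and 2 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.0219, adjusted p = 0.188 with an estimated correlation). The desaturase SCD was at 1.13 and the elongase ELOVL5 at 1.57. Fatty acid oxidation genes went both ways (8 of 22 rose and 8 fell, 8 and 8 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.90), their median -0.14 and mean 0.017. Cholesterol biosynthesis genes fell (15 of 24 fell and 1 rose, 16 and 2 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.00209, adjusted p = 0.293 with an estimated correlation). Integrated stress genes rose (21 of 31 rose and 8 fell, 21 and 8 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.00375, adjusted p = 0.261 with an estimated correlation). TRIB3 was at 2.36 and ASNS at 2.26. S phase genes fell (28 of 43 fell and 2 rose, 28 and 2 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 4.0e-05, adjusted p = 0.330 with an estimated correlation). G2/M genes fell (47 of 54 fell and 1 rose, 49 and 1 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 1.9e-12, adjusted p = 0.188 with an estimated correlation). The PARP inhibitor response list fell (13 of 20 fell and 2 rose, 13 and 2 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.0158, adjusted p = 0.463 with an estimated correlation). Here the median of -0.34 and the mean of 0.12 had opposite signs. Interferon genes did not pass (16 of 44 fell and 13 rose, 16 and 13 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.930), with a median of 0.021 and a mean of -0.038. In all, 8941 of 13330 genes changed, 4495 higher and 4446 lower. Scaling by library totals alone gave 4056 higher and 4981 lower. The mesothelial call was lost with G1 cells alone (camera, Benjamini-Hochberg adjusted p = 0.0509).

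At 320 µM the adapted cells had the most changed genes of the 4 treated conditions (9930 of 13330 genes changed, 5012 higher and 4918 lower). CD70, a ligand of the TNF family (GRCh38 chromosome 19, 6583183 to 6604103), rose from 3.65 ± 0.352 to 251 ± 1.55 CPM (log2 change 6.10). The potassium channel KCNMA1 (67.3 ± 2.11 against 0.994 ± 0.154 CPM, log2 change 6.07), the hypoxia-induced mitochondrial gene NDUFA4L2 (57.9 ± 3.48 against 0.930 ± 0.0645 CPM, log2 change 5.94), the laminin chain LAMA4 (5.18), the phosphodiesterase PDE1C (4.86) and CD44 (383 ± 11.4 against 16.6 ± 0.000809 CPM, log2 change 4.53) rose alongside. SPINT2, an epithelial protease inhibitor (GRCh38 chromosome 19, 38244035 to 38292614), fell from 348 ± 6.42 to 10.5 ± 0.691 CPM (-5.05). Mesothelin MSLN (2.34 ± 0.215 against 85.7 ± 3.56 CPM, log2 change -5.18) and the cadherin CDH6 (14.2 ± 0.348 against 507 ± 12.8 CPM, log2 change -5.16) fell likewise, and SOX17 went from 325 ± 50.2 to 5.67 ± 1.91 CPM. FLG (-7.08), APOA1 (-6.17), LYPD1 (-5.75) and LEMD1 (-5.75) were lower as well.

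Ovarian serous lineage genes fell (14 of 15 fell and 1 rose, 14 and 1 adjusted over the list alone, median log2 change -4.40, camera, Benjamini-Hochberg adjusted p = 1.5e-05, adjusted p = 0.215 with an estimated correlation), with the transcription factors EMX2 at -4.28, MECOM at -4.51 and WT1 at -4.77. Epithelial genes fell (19 of 21 fell and 1 rose, 19 and 1 adjusted over the list alone, median log2 change -3.45, or -3.36 with thinly counted members at their bound, camera, Benjamini-Hochberg adjusted p = 6.4e-05, adjusted p = 0.151 with an estimated correlation). CLDN3 was at -3.82 and KRT8 at -1.37. Mesenchymal genes rose (19 of 28 rose and 7 fell, 19 and 7 adjusted over the list alone, median log2 change 1.37, camera, Benjamini-Hochberg adjusted p = 0.00533, adjusted p = 0.218 with an estimated correlation). TGFBI was at 5.26 and FN1 at 3.89. Fibroblast markers did not pass (4 of 13 fell and 3 rose, 4 and 3 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.947). Hypoxia and glycolysis genes rose (23 of 28 rose and 3 fell, 23 and 3 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 1.5e-05, adjusted p = 0.281 with an estimated correlation), including the mitophagy receptor BNIP3 (398 ± 15.2 against 82.7 ± 0.263 CPM, log2 change 2.27) and VEGFA (2.03). NRF2 targets rose (17 of 23 rose and 3 fell, 17 and 3 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 5.5e-04, adjusted p = 0.215 with an estimated correlation). TXNRD1 was at 1.84 and the transketolase TKT at 2.08. Integrated stress genes rose (23 of 31 rose and 5 fell, 23 and 5 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 3.6e-05, adjusted p = 0.215 with an estimated correlation). DDIT4 was at 3.87. Interferon genes fell (27 of 44 fell and 5 rose, 27 and 5 adjusted over the list alone, median log2 change -0.77, or -0.72 with thinly counted members at their bound, camera, Benjamini-Hochberg adjusted p = 3.1e-04, adjusted p = 0.237 with an estimated correlation). BST2 was at -3.85. Large ribosomal protein genes rose (38 of 41 rose and 1 fell, 38 and 1 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 1.1e-18, adjusted p = 0.215 with an estimated correlation). Homologous recombination genes did not pass (12 of 31 fell and 7 rose, 11 and 6 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.541), with a median of 0.034 that turned negative under library totals alone and FANCL at -1.58. XRCC1 and LIG1, which act in the repair of single-strand breaks, were at -1.42 and -2.65.

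CDKN2A, which encodes a cyclin-dependent kinase inhibitor, fell from 845 ± 34.6 CPM in control to 22.6 ± 1.01 in 320 µM adapted cells (-5.22). Its neighbours on the short arm of chromosome 9 (GRCh38, GENCODE 29) were looked up after that value was seen. MTAP (21802543 to 21937651) stood at 2.57 ± 0.710 against 71.2 ± 1.21 CPM and CDKN2B (22002903 to 22009363) at 0.510 ± 0.0700 against 11.7 ± 0.800, on either side of CDKN2A (21967753 to 21995301). Of the 12 other tested genes within 3 Mb, 6 were lower in 320 µM adapted cells, 2 higher and 4 not past the test. The lower ones lay on both sides, with log2 changes of -0.24 for KLHL9, -1.73 for IFNE, -2.87 for HACD4, -0.88 for FOCAD and -1.92 for PLIN2 on the side of MTAP and -0.83 for DMRTA1 on the other. HAUS6 (19053143 to 19103119), the neighbour of PLIN2, stood at 49.2 ± 1.74 against 49.7 ± 0.0200 CPM. In 10 µM adapted cells 11 of these 12 were lower and 0 higher. There CDKN2A was at 246 ± 6.04, MTAP at 18.1 ± 0.400 and HAUS6 at 23.2 ± 0.670 CPM. Along the genome, medians of 100 neighbouring genes spread more in adapted than in persister cells. Their variance over 122 windows was 16.1 times the mean of 1000 shuffles of gene order at 320 µM and 14.8 times at 10 µM, against 1.86 and 3.85 times in the persister cells, with 0 shuffles as large in each. In 320 µM adapted cells the lowest window was chromosome 1 from 109483479 to 149812373 (median log2 change -1.13) and the highest was chromosome 19 from 49665142 to 55117559 (1.62). There 10 µM adapted cells had -0.69 and 0.92. Scaled by library totals alone, 3726 genes were higher and 6233 lower in 320 µM adapted cells, and the median of all genes moved by -0.23 on the log2 scale. The directions above were relative to that median.

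**Figure D2:**
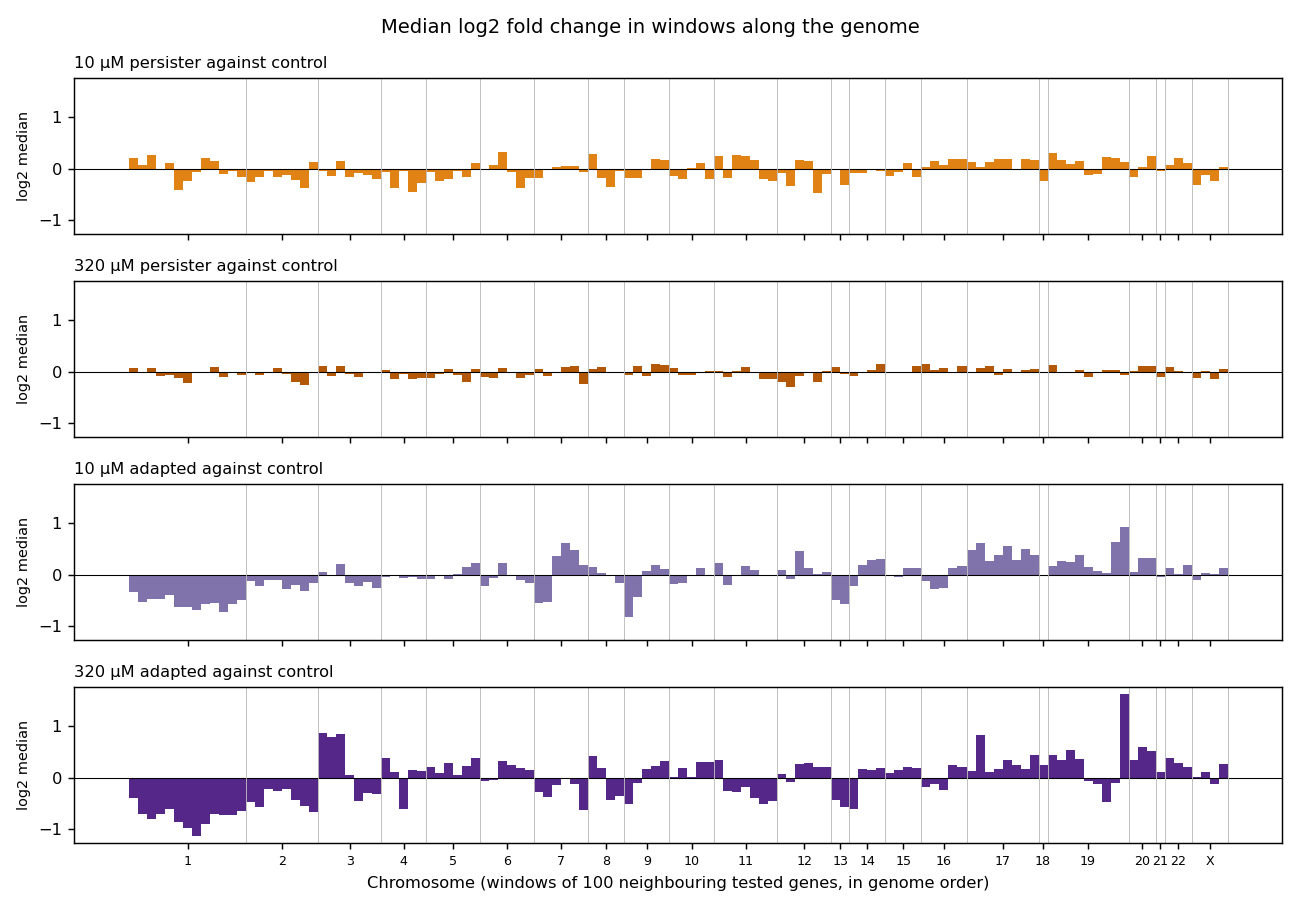
Median log2 change of windows of 100 neighbouring tested genes along the genome (x axis, chromosomes in order) for each treated condition against control (y axis, log2). The highest window of 320 µM adapted cells lies on chromosome 19 at 1.62, and the lowest on chromosome 1 at -1.13.

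Adapted cells were next set against persister cells of the same dose. At 10 µM the inflammatory genes of persister cells were low again in adapted cells, CXCL10 at 2.37 ± 0.208 against 785 ± 92.8 CPM (log2 change -8.37), SAA1 at 1.20 ± 0.218 against 167 ± 0.0637 and RSAD2 at 0.324 ± 0.0888 against 118 ± 39.5. The chemokine CCL20 (-7.31), the chitinase-like CHI3L1 (-8.02) and the interferon-induced XAF1 (-7.15) fell with them. Higher in adapted cells were COL1A1 at 92.2 ± 1.99 against 2.49 ± 0.125 CPM, TGFBI at 127 ± 0.154 against 1.24 ± 0.290, VCAM1 (5.55), PCOLCE (5.31), COL3A1 (3.82) and ACTA2 (4.50). FN1 was high in both, at 665 ± 28.7 and 764 ± 68.4 CPM.

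Among 44 interferon genes 43 fell and 1 rose, 43 and 1 adjusted over the list alone (median log2 change -4.71, camera, Benjamini-Hochberg adjusted p = 1.6e-33). Among 27 NF-kB genes 26 fell and 0 rose, 26 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.6e-20). Among 17 MHC class I genes 16 fell and 0 rose, 16 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.4e-12). NRF2 targets fell (18 of 23 fell and 3 rose, 19 and 3 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 2.2e-07). FTH1 was at -2.64. Apoptosis regulators fell (15 of 23 fell and 3 rose, 15 and 3 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 7.7e-04). BIRC3 was at -5.28 and BAK1 at -2.04. Epithelial genes fell (14 of 21 fell and 1 rose, 14 and 1 adjusted over the list alone, median log2 change -1.29, camera, Benjamini-Hochberg adjusted p = 2.6e-05). ELF3 was at -3.70. All 41 large ribosomal protein genes were higher (41 adjusted over the list alone, median log2 change 1.35, camera, Benjamini-Hochberg adjusted p = 8.4e-38). Of 13 mitochondrially encoded genes 12 rose and 0 fell, 12 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 4.7e-09). Cell cycle genes were higher, TOP2A at 1.79. In the G2/M list 47 of 54 rose and 3 fell, 48 and 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 6.7e-13, adjusted p = 0.0981 with an estimated correlation). In the S phase list 32 of 43 rose and 3 fell, 32 and 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.8e-05, adjusted p = 0.252 with an estimated correlation). These 2 lists were no longer called among G1 cells (camera, Benjamini-Hochberg adjusted p = 0.0839 and 0.0615). Phases were called from these same lists, so that choice of cells can by itself end the calls. PARP1 and CDKN1A were not past the test (-0.072 and 0.031, edgeR, Benjamini-Hochberg adjusted p = 0.223 and 0.827). PARP1 was lower under library totals alone (-0.26, edgeR, Benjamini-Hochberg adjusted p = 3.2e-05).

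In all, 8094 of 13330 genes changed, 4190 higher and 3904 lower. Under library totals alone 3137 genes were higher and 4920 lower, with the median of all genes moved by -0.19 on the log2 scale. S100A8 had 546 UMIs in 10 µM persister and 1 in 10 µM adapted cells, a ratio of 796 at the floor of 3 UMIs and of 2388 as counted, with an exact 95% interval of 427 to 94505. Its call was lost without the adapted sum of pool 1 (-12.8) or of pool 2 (-9.81). That of S100A9 was lost with the 4 compared sums alone (edgeR, Benjamini-Hochberg adjusted p = 0.0516).

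For 320 µM the same contrast showed gains of CD70 (251 ± 1.55 against 7.0 ± 1.63 CPM, log2 change 5.17), LAMA4 (95.8 ± 4.40 against 1.85 ± 0.510 CPM, log2 change 5.69), PDE1C (5.15), KCNMA1 (4.57), the fatty acid binding protein FABP5 (169 ± 9.29 against 7.51 ± 0.899 CPM, log2 change 4.49) and FN1 (3.87) in adapted over persister cells. Ceruloplasmin CP (4.12 ± 0.817 against 179 ± 17.2 CPM, log2 change -5.45), MSLN (-5.24), the claudins CLDN3 (-5.21) and CLDN4 (-4.53), SPINT2 (-4.53) and CDKN2A (-4.26) were lower. TPPP3, high in persister cells, was at 5.94 ± 0.0193 against 218 ± 1.55 CPM. Osteopontin, encoded by SPP1, changed by -4.24 and SOX17 by -5.14.

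Mesenchymal genes were higher (22 of 28 rose and 0 fell, 22 and 0 adjusted over the list alone, median log2 change 1.30, camera, Benjamini-Hochberg adjusted p = 1.5e-07, adjusted p = 0.0914 with an estimated correlation). Epithelial genes were lower (16 of 21 fell and 1 rose, 16 and 1 adjusted over the list alone, median log2 change -2.21, or -2.09 with thinly counted members at their bound, camera, Benjamini-Hochberg adjusted p = 9.8e-05, adjusted p = 0.0914 with an estimated correlation). Serous lineage genes were lower too (14 of 15 fell and 1 rose, 14 and 1 adjusted over the list alone, median log2 change -2.93, or -2.56 with thinly counted members at their bound, camera, Benjamini-Hochberg adjusted p = 8.9e-05, adjusted p = 0.154 with an estimated correlation). EMX2 was at -4.12 and PAX8 at -1.37. G2/M genes were higher (48 of 54 rose and 2 fell, 49 and 2 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 3.5e-14, adjusted p = 0.141 with an estimated correlation). UBE2C was at 2.68 and CDC20 at 1.88. The G2/M list call was lost in G1 cells (camera, Benjamini-Hochberg adjusted p = 0.401), which were themselves chosen by low scores of these genes. Hypoxia and glycolysis genes were higher (25 of 28 rose and 1 fell, 25 and 1 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 7.6e-09, adjusted p = 0.154 with an estimated correlation). BNIP3 was at 1.96 and the peptide hormone ADM at 1.81. Immediate early genes were higher (14 of 21 rose and 1 fell, 15 and 2 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 2.6e-04, adjusted p = 0.151 with an estimated correlation). FOSL1 was at 3.78 and DUSP1 at 1.53. MYC targets and ribosome biogenesis genes were higher (23 of 32 rose and 2 fell, 23 and 2 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 7.2e-06, adjusted p = 0.141 with an estimated correlation). Mitochondrially encoded genes were lower (12 of 13 fell and 1 rose, 12 and 1 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 5.8e-06, adjusted p = 0.141 with an estimated correlation). Homologous recombination genes were higher (17 of 31 rose and 2 fell, 17 and 2 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.0493, adjusted p = 0.429 with an estimated correlation). FANCD2 was at 1.55. That list call was lost with the replicate number as a block (camera, Benjamini-Hochberg adjusted p = 0.0761) and in G1 cells (adjusted p = 0.600). Integrated stress genes went both ways (15 of 31 fell and 8 rose, 15 and 9 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.358). The serine synthesis enzymes PHGDH and PSAT1 were at -2.07 and -1.42.

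In all, 8891 of 13330 genes changed, 4548 higher and 4343 lower. Under library totals alone 3027 were higher and 5995 lower, with a median shift of -0.28 on the log2 scale. CDKN1A was 0.31 higher on the log2 scale. That call was lost without the persister sum of pool 1 (0.16) and under library totals alone (0.024, edgeR, Benjamini-Hochberg adjusted p = 0.802).

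The adapted populations were compared, but dose cannot be told apart from other differences between them. Some genes that were high in 10 µM adapted cells were low again at 320 µM. COL1A1 stood at 0.883 ± 0.346 against 92.2 ± 1.99 CPM (log2 change -6.71), BGN at 0.447 ± 0.189 against 58.4 ± 4.66, VCAM1 at 1.33 ± 0.327 against 105 ± 4.50, and SULF1, a sulfatase of heparan sulfate, changed by -6.64. TGFBI and FN1 were lower (-1.51 and -1.66) but stayed above control. The mesenchymal list, with a median of -0.31, did not pass (15 of 28 fell and 8 rose, 15 and 8 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.0574). It passed with the replicate block (camera, Benjamini-Hochberg adjusted p = 0.0227). With an estimated correlation 0 lists passed in the main fit. Higher at 320 µM were the neuritin gene NRN1 (298 ± 6.21 against 16 ± 1.87 CPM, log2 change 4.22), NDUFA4L2 (3.78), heme oxygenase HMOX1 (158 ± 9.12 against 15.3 ± 2.02 CPM, log2 change 3.36) and CD70 (2.95).

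All 28 hypoxia and glycolysis genes were higher (28 adjusted over the list alone, median log2 change 0.86, camera, Benjamini-Hochberg adjusted p = 2.2e-11, adjusted p = 0.175 with an estimated correlation). NDRG1 was at 2.64. NRF2 targets were higher (16 of 23 rose and 3 fell, 16 and 3 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 1.8e-05, adjusted p = 0.113 with an estimated correlation). TXNRD1 was at 2.55. Serous lineage genes were lower (14 of 15 fell and 0 rose, 14 and 0 adjusted over the list alone, median log2 change -3.56, camera, Benjamini-Hochberg adjusted p = 1.3e-07, adjusted p = 0.162 with an estimated correlation). So were epithelial genes (16 of 21 fell and 2 rose, 16 and 2 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 4.0e-05, adjusted p = 0.113 with an estimated correlation). Fibroblast markers were also lower (11 of 13 fell and 1 rose, 11 and 1 adjusted over the list alone, median log2 change -2.31, camera, Benjamini-Hochberg adjusted p = 3.1e-04, adjusted p = 0.113 with an estimated correlation). Interferon genes were lower (29 of 44 fell and 2 rose, 30 and 2 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 2.7e-06, adjusted p = 0.175 with an estimated correlation). BST2 was at -4.25. G2/M genes were higher (39 of 54 rose and 4 fell, 39 and 4 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 7.0e-07, adjusted p = 0.267 with an estimated correlation). In G1 cells, which were chosen by low scores of these genes, their median turned to -0.28. In all, 8766 of 13330 genes changed, 4449 higher and 4317 lower. Under library totals alone 3230 were higher and 5391 lower, with a median shift of -0.16 on the log2 scale.

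The difference between these dose effects was then tested, with the same limit for adapted cells. The dose effect differed for 6577 of 13330 genes, more positive in adapted cells for 3124 and more negative for 3453, or 2707 and 3926 under library totals alone. Interferon genes were among the former (41 of 44 higher and 1 lower, 41 and 1 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 2.4e-28). NF-kB genes were too (25 of 27 higher and 0 lower, 25 and 0 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 2.3e-19). So were MHC class I genes (16 of 17 higher and 0 lower, 16 and 0 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 3.7e-16). Hypoxia and glycolysis genes were lower with dose in persister cells and higher in adapted cells (27 of 28 higher and 0 lower, 27 and 0 adjusted over the list alone, median log2 change 1.87, camera, Benjamini-Hochberg adjusted p = 2.3e-19, adjusted p = 0.0731 with an estimated correlation), with SLC2A1, a glucose transporter, at -1.76 in persister cells and a difference of 2.58. Mitochondrially encoded genes had a more negative dose effect in adapted cells (13 of 13 lower and 0 higher, 13 and 0 adjusted over the list alone, median log2 change -1.24, camera, Benjamini-Hochberg adjusted p = 4.4e-15). So had serous lineage genes, whose medians were lower with dose in both persister and adapted cells, -1.14 and -3.56 (11 of 15 lower and 1 higher, 11 and 1 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 1.7e-04, adjusted p = 0.183 with an estimated correlation). The imprinted gene PEG10 had 41.6 ± 2.79 and 127 ± 8.18 CPM in 10 and 320 µM persister cells and 172 ± 0.527 and 18.0 ± 1.12 in adapted cells, a difference of -4.87 on the log2 scale.

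**Figure D3:**
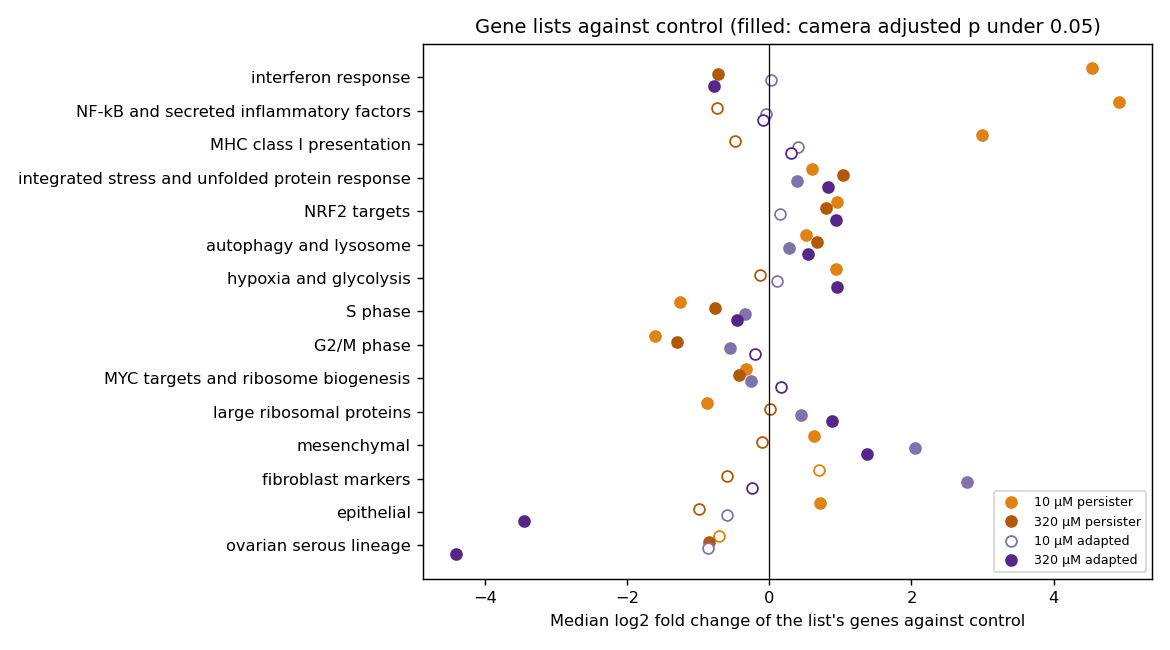
Median log2 change against control (x axis) of 15 gene lists (y axis) in the 4 treated conditions. Filled points passed the camera test with a Benjamini-Hochberg adjusted p under 0.05 and open points did not, with the preset correlation of 0.01 in each case. The interferon median is 4.54 in 10 µM persister cells and -0.77 in 320 µM adapted cells.

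**Figure D4:**
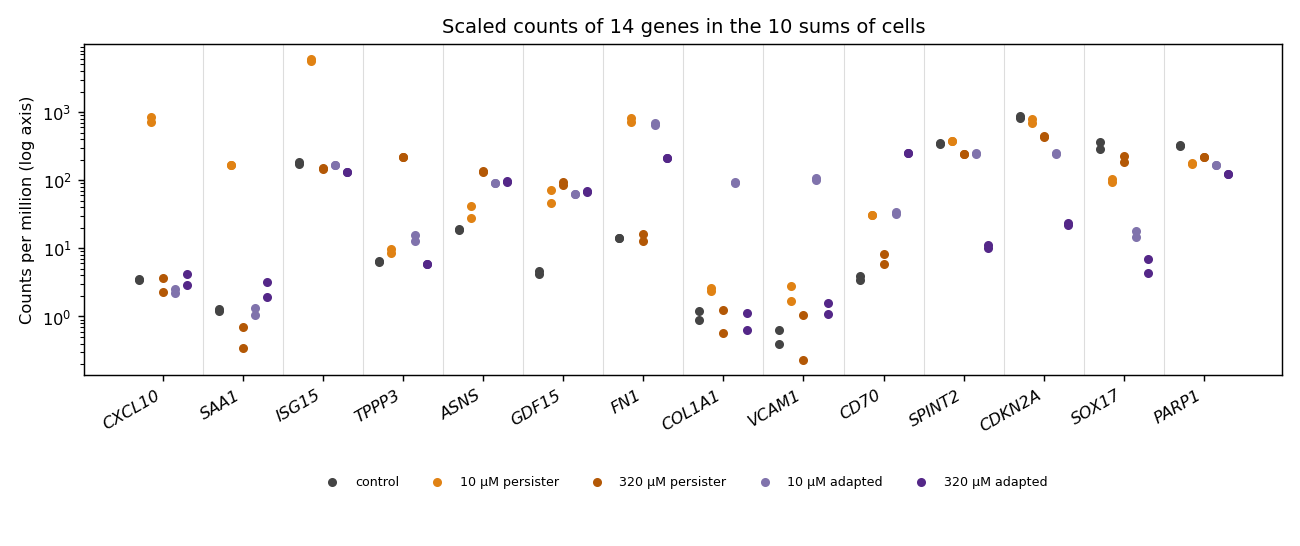
CPM of 14 genes (log axis) in the 10 sums, grouped by condition. Points are single sums, 2 per condition. CXCL10, SAA1 and ISG15 are highest in 10 µM persister cells, TPPP3 in 320 µM persister cells and COL1A1 and VCAM1 in 10 µM adapted cells, and CDKN2A is lowest in 320 µM adapted cells.

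Whether persister and adapted cells of 1 dose changed the same genes was asked by overlap. At 10 µM 1778 genes were higher and 2244 lower in both, among them the lower PARP1, CLSPN and NMU, against 1227 and 1304 for independent lists, and 1486 genes were changed in opposite directions against 2532. At 320 µM 2033 genes, such as CD44 and TRIB3, were higher and 2433, such as APOA1 and LYPD1, lower in both, against 1320.5 and 1391, and 1449 were opposite against 2713. Both comparisons at a dose used the same control sums, which raises such overlaps by chance. In 100 simulations of unchanged groups against those controls at most 3 genes were shared in a direction. Unchanged groups give few calls, so that number cannot say how much of the overlaps the shared controls caused. The covariance of log2 changes across genes was 0.485 at 10 µM and 0.607 at 320 µM, against simulated means of 0.0148 and 0.0151. Pearson's r across genes, which are not independent replicates, was 0.300 and 0.440, against simulated means of 0.231 and 0.367. With no sum shared between the comparisons r was 0.286 and 0.302 at 10 µM and 0.438 and 0.436 at 320 µM. With only 2 control sums the controls could not be split into parts of 2, so part of the excess in the overlaps may come from them.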

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

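The test of depth was chosen only after results were seen, in place of one on the 10 largest rises, which were picked for rising. Other tests here were written before being run, for patterns in these data. The dose effect, 320 µM against 10 µM, was tested for a difference between adapted and persister cells. It differed for 6577 of 13330 genes (edgeR, Benjamini-Hochberg adjusted p under 0.05). As log2 differences with that adjusted p in brackets, the largest positive ones among named genes were SAA2 by 9.43 (1.8e-14), SAA1 by 9.41 (3.0e-18), RSAD2 by 9.03 (0.00177), CXCL10 by 8.66 (3.2e-10) and HP by 7.84 (5.0e-06). The largest negative ones were TPPP3 by -5.83 (2.5e-22), COL1A1 by -5.29 (1.1e-08), BGN by -5.03 (9.5e-07), SLIT3 by -4.97 (1.3e-23), which guides axons, and PEG10 by -4.87 (4.7e-26). SLIT3 and PEG10 rose with dose in persister cells and fell with it in adapted cells. Of the others, 1 condition stood above the rest: 10 µM persister cells for the 5 positive ones, 320 µM persister cells for TPPP3 and 10 µM adapted cells for COL1A1 and BGN. The call of HP was lost with thinned sums (log2 difference 6.24, adjusted p = 1.000), where the 320 µM persister cells held 2 HP UMIs before thinning. That of MKI67 (-0.41) was lost without the 10 µM persister sum of pool 1 (-0.29). Groups of 2 sums are too small for a test of outlying sums.

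The named positive differences come from genes that were high in 10 µM persister cells, where all 44 interferon response genes and all 27 NF-kB genes rose. Leukocytes carried into that condition are argued against, since 7 leukocyte transcripts summed to at most 0.0243 of the CXCL10 level, under the tenth set as a bound, with CD68 at 12.2 and 15.2 CPM and CORO1A at 5.38 and 6.14. Deeper cells are argued against, because at 3000 UMIs per cell the median share of cells with a UMI, over all members of either list, was at least 13.1 times that of control in both pools. It was 40.7% and 43.5% against 2.66% and 2.22% for the interferon list and 19.4% and 23.1% against 1.49% and 1.31% for the NF-kB list. A lower share of cycling cells is not the whole cause, as the interferon list had a median log2 change of 4.38 in G1 cells against 4.54 over all cells (camera, Benjamini-Hochberg adjusted p = 2.1e-40 in G1 cells). Innate immune signalling in cells that survive the lower dose may account for the pattern, a hypothesis on data that also raised it, and a difference in culture between the doses, such as cell density, was not measured and stays open.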

How the results depend on the processing

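Alternatives chosen after seeing the data are named above. Counts are given below in the order 10 µM persister, 320 µM persister, 10 µM adapted and 320 µM adapted against control, adapted against persister at 10 and at 320 µM, 320 against 10 µM in persister and in adapted cells, and the difference of dose effects. Counts of changed genes were 0.256 to 1.07 times the main ones over all alternatives. They were lowest with at least 2-fold changes, by construction: 2928, 1864, 2835, 4071, 3397, 3457, 2328, 2618 and 3016. With sums thinned to the smallest total, 3 counts moved by over 1.5 times, to 4667, 5507 and 5366 from 7282, 8941 and 8766, since thinning leaves fewer counts. At 2-fold, genes changed the same way in persister and adapted cells fell to 617 higher and 291 lower at 10 µM and 464 and 570 at 320 µM. Leaving out 1 sum gave 6288 to 7023, 5942 to 6359, 7876 to 8072, 9091 to 9265, 6828 to 7494, 7871 to 8224, 5496 to 5873, 7723 to 7870 and 5860 to 6146 changed genes, where the lone sum left is assumed to vary like the other groups. With the replicate number as a block the counts were 7811, 7792, 9443, 10319, 8288, 9215, 6855, 9238 and 6902. The homologous recombination call in 320 µM adapted against persister cells was then lost, as given above. ACSL3 in 10 µM persister cells passed with the block (log2 change -0.15, edgeR, Benjamini-Hochberg adjusted p = 0.0463). The block ended no other call of a list and changed that of no other named gene, but of 288 list tests 13 that had not passed did so with it, such as the mesenchymal list in 320 against 10 µM adapted cells. With G1 cells 9 did. Whether more genes were higher or lower turned under library totals alone in every comparison but the difference of dose effects.

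Camera called 19, 17, 15, 12, 19, 15, 18, 12 and 15 lists with the preset correlation. It called 8, 0, 0, 0, 8, 0, 10, 0 and 5 with an estimated correlation, and 13, 9, 8, 7, 12, 9, 12, 8 and 10 then had an unadjusted p under 0.05. Fry called 30, 27, 26, 32, 32, 30, 30, 26 and 24. Fry asks only whether a list's genes move on balance 1 way. Over 142 list results 433 alternative values kept direction and call, 132 lost the call (111 with an estimated correlation, 20 with G1 cells) and 3 turned direction. Over 1217 results for named genes 19313 kept both, 568 lost the call (381 of them at 2-fold), 19 gained it and 31 turned.

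Which genes and lists turned is given next, and the cause was not tested. In G1 cells alone, median log2 changes turned for S phase in 320 against 10 µM persister cells (-0.092) and for G2/M in the same comparison (-0.26) and in 320 against 10 µM adapted cells (-0.28). Against control, genes that turned in G1 cells were DYNLL1 (0.010) and FADS1 (0.12) in 320 µM persister cells, MT1X in 10 and 320 µM adapted cells (-0.28 and -0.38) and BRCA2 in 320 µM adapted cells (-1.01). In adapted against persister cells at 10 µM they were BRCA2 (-0.72), UBE2C (-0.035) and DYNLL1 (-0.062, and -0.055 under library totals alone). In 320 against 10 µM adapted cells they were BRCA2 (-0.28), CDK1 (-0.077), MT2A (-0.043) and MT1X (-0.092). MKI67 turned in 320 against 10 µM persister cells (-0.44) and in the difference of dose effects (0.35). The cells of the deposited list turned FADS1 (0.14), MT1X (-0.26 and -0.36) and BRCA2 (-0.88) against control in the same conditions. In adapted against persister cells at 10 µM they turned BRCA2 (-0.82), UBE2C (-0.21) and DYNLL1 (-0.063). They also turned BRCA2 (-0.26), CDK1 (-0.035), MT2A (-0.10) and MT1X (-0.11) between adapted doses, MKI67 between persister doses (-0.61) and in the difference of dose effects (0.55). Against control BRCA2 (0.21) and PARP2 (0.011) turned in 10 µM persister cells and PARP2 in 10 µM adapted cells (0.056). Past the test in the new direction were BRCA2 in 320 µM adapted cells and between states at 10 µM, MT1X in both adapted conditions (each in both settings) and MT2A in listed cells. The share of cells in S or G2/M moved beyond its SD without thinning in 10 µM persister cells (23.3% from 21.1%) and 320 µM adapted cells (45.3% from 43.9%), and in no condition with the stricter cell filter. Depth limits the 10 µM persister sums most, where 3 UMIs stand for up to 0.849 CPM.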

Other observations

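The grouping of 10 µM adapted cells, its windows, the test of another origin and the per-gene ratios in cells with COL1A1 were chosen only after results were seen. Tests of fibroblasts and of G1 cells were written before being run. That of MTAP was written after the fall of CDKN2A was seen but before MTAP was looked at. Adapted cells at 10 µM fell into 3 groups when clustered on their own at a resolution chosen after a trial clustering of all cells. In pools 1 and 2, group 1 held 47.1% and 45.1%, group 2 44.0% and 46.5% and group 3 8.91% and 8.38% of these cells. MECOM, REC8 and the protease inhibitor SPINT2 led group 1 and VCAM1 and COL1A1 were high outside it, which follows from grouping on expression. COL1A1 stood at 7.56 ± 1.66, 109.9 ± 3.33 and 534 ± 3.40 CPM (n = 2) in groups 1 to 3, and VCAM1 at 2.16 ± 1.60, 146 ± 6.70 and 564 ± 15.3. CDKN2A, MTAP and PAX8 did not lead a group. As percent of control, CDKN2A was at 44.0% in group 1, 4.06% in group 2 and 22.6% in group 3. MTAP was at 38.5%, 4.12% and 18.0%, and the lineage factor PAX8 at 78.8%, 22.7% and 8.12%. Adapted cells at 320 µM had 2.29%, 3.09% and 32.7% of these genes. For SPINT2, MECOM and REC8 they had 2.59%, 3.71% and 2.65%, against 10.1%, 2.08% and 3.01% in group 2. These levels are CPM of summed cells without further scaling.

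Mesenchymal genes were higher in 10 µM adapted cells, and a COL1A1 UMI was found in 273 of 1796 cells of pool 1 and 259 of 1563 of pool 2 at 3000 UMIs. A lower share of cycling cells is argued against as the whole cause. The list had a median log2 change of 2.03 in G1 cells (camera, Benjamini-Hochberg adjusted p = 1.1e-09) against 2.04 over all. With an estimated correlation 0 of the 15 list calls over all cells held. Fibroblasts could not be excluded: 6 epithelial and line transcripts summed to 1.41 and 1.48 times the level of other cells in cells with COL1A1, above the bound set against fibroblasts. That sum rests on the keratins KRT8 (1.63 and 1.63) and KRT18 (1.65 and 1.54), while PAX8 (0.491 and 0.458), MECOM (0.0876 and 0.123), EPCAM (0.211 and 0.599) and CDKN2A (0.603 and 0.667) were lower in both pools. A shift of part of the line to a mesenchymal state, as a hypothesis, and cells of another origin both stay open.

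Neighbouring genes shifted together in adapted cells, and copy number differences from control are a candidate explanation. The excess variance of window medians was 3.70 times that of persister cells at 10 µM and 45 times at 320 µM, and MTAP, beside CDKN2A, stood at 3.61% of control in 320 µM adapted cells, as loss of a segment of chromosome 9 would give. Groups 1 and 2 of the 10 µM adapted cells differed in the same way, with a variance 17.1 times the shuffled mean, and the window profiles of the groups against control correlated with that of 320 µM adapted cells at 0.593 and 0.562 for group 1, 0.800 and 0.795 for group 2 and 0.681 and 0.616 for group 3, each against the other pool, where the same group reached 0.981, 0.987 and 0.953 between pools. Whether some adapted cells had another origin than the control line cannot be told apart from selection of clones: the lower value of 0.562 for group 1 lies between the bounds set for each, and cells of another line would shift windows too. Expression gives no genotype, and levels of 2 to 4% of control may also be free RNA or wrongly assigned cells.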
